A study of Mus musculus with 4 samples.

How the data were processed

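Gene expression was measured by RNA sequencing in 4 libraries of mouse satellite cells, 2 infected with CPEB4 virus and 2 with GFP virus. Per the labels' protocols the cells were isolated from muscle by fluorescence-activated sorting and the libraries made from total RNA with the SMART-seq2 method, and the series' design text names a BGI DNBSEQ-G400 instrument and paired reads. Groups came from the treatment label of each sample, and columns of the tables were assigned by the sample titles.

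The deposited count table holds whole-number read counts per gene symbol for 55376 symbols, with 1 column per library and no pooled column. Per the submitters' processing notes the tools were HISAT2 and featureCounts and the genome build was mm10. Their versions and settings, the annotation, any trimming and the treatment of reads that map to several places are not given in the sources used here. SMART-seq2 does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart. Genes with near-identical copies, such as ribosomal protein genes with their pseudogenes or the actin genes, may have lost or shared reads in a way that the sources do not state, and their counts are uncertain for that reason. The second deposited table holds FPKM values for the same genes and libraries, which the authors had normalized by gene length in kilobases and by a library total. Dividing each count by its FPKM value and by the union exon length in GENCODE release M21 gave 1 library total per column, of 24240818, 22453218, 32212976 and 41045926 in the order GFP 1, GFP 2, CPEB4 1 and CPEB4 2, and at least 99.2% of genes with at least 20 counts lay within 1% of it. The deposited counts were 16%, 16.7%, 26% and 19.1% below these totals, reads that had entered the total without being counted in a gene of the table. Gene identifiers, positions and exon lengths were taken from GENCODE release M21, which is on the same build and holds 54510 of the symbols.

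The count totals were 20358858 and 18694577 for GFP virus and 23831920 and 33193475 for CPEB4 virus. A floor of 3 counts corresponded to 0.16, 0.203, 0.105 and 0.0795 TMM-scaled CPM in the same order. Reads carried no molecular identifiers, so intervals and floors cover counting error only. The replicates of a group were compared by a chi-square test over genes, which gave 87 per degree of freedom for GFP virus and 12.5 for CPEB4 virus, so neither pair was the same library deposited again.

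Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, using TMM factors (0.92, 0.793, 1.203 and 1.139), the default filter by group (filterByExpr, minimum count 10 and minimum total 15) and the two-sided quasi-likelihood test with Benjamini-Hochberg adjustment over 16870 tested genes at 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The biological coefficient of variation was 21.8% in this fit, 28.9% within the GFP libraries and 11.6% within the CPEB4 libraries. The 38 gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 members were tested, which held for 37 lists, with Benjamini-Hochberg adjustment over these. Camera was repeated with the correlation estimated per list. Values named for single genes followed a rule set before the data were examined, namely Cpeb4, the 12 genes in each direction with the smallest p among called, non-overlapping, named genes that are not pseudogenes or small RNAs, up to 4 members of each list with the smallest p, and Pax7, Myod1, Myog, Cdkn1a, Cdkn2a and Mki67. Where 5 or fewer members of a list moved in a direction, all are named, and those outside the rule were chosen after their values were seen. A fold against a group with 0 counts was computed against 3 counts over the group, and a ratio with 1 to 3 counts in a group has an exact binomial interval.

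The fit was tested on simulated counts for 16344 genes drawn from the means and library sizes of the real comparison with 194 changed genes. It recovered 37.8% of 2-fold and 83.3% of 4-fold changes, 5 of its 122 calls were false (4.1%), and camera called the 1 list that had been moved and 0 others. Genes were drawn independently, so the simulation does not test camera where members of a list vary together. In the real data the estimated correlation was 0.939 for ribosomal proteins and 0.87 for complex I. Alternatives set before the data were examined were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, no low-count filter, a mean of at least 5 CPM, a replicate block, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1, and each library left out in turn. Added after seeing the data were library totals alone, the removal of each library's trend with exon length or with GC content by a loess offset (span 0.3), and the subtraction of a background density per exonic kb estimated on olfactory and vomeronasal receptor genes. Figures were drawn with matplotlib 3.10.9.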

Results

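Satellite cells, the stem cells of skeletal muscle, had been sorted by flow cytometry from C57BL/6 mice aged 33 months and infected either with a CPEB4 virus or with a GFP virus as the control. CPEB4 is an RNA-binding protein that recognises the cytoplasmic polyadenylation element in 3' untranslated regions and regulates translation. RNA was measured in 2 libraries per group by SMART-seq2, a full-length cDNA method for small amounts of RNA. The kind of virus, its dose and the time from infection to collection are not given in the sources used here. No source states which animals stand behind each library, so p-values measure the spread between these libraries, which may be technical. The question set by the design was which transcripts differ in geriatric satellite cells after CPEB4 virus infection.

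The deposited counts summed to 20358858 in GFP library 1, 18694577 in GFP library 2, 23831920 in CPEB4 library 1 and 33193475 in CPEB4 library 2. The libraries also differed in ways that follow the groups. A count was seen for 25578 and 26431 genes in the GFP libraries and for 40091 and 33943 genes in the CPEB4 libraries. After thinning to the smallest total the CPEB4 libraries still held 38542 and 30611 genes, against 25245 and 26431. Olfactory receptor genes held 28.7 CPM (counts normalised to the library total) in GFP library 1 (95% exact Poisson interval 26.5 to 31.2) and 27.8 in GFP library 2 (25.5 to 30.3). They held 227 (221 to 233) and 62.1 (59.5 to 64.9) CPM in CPEB4 libraries 1 and 2. Such intervals, here and below, cover counting error only. Genes of the mitochondrial genome held 0.567% and 0.539% of the counts in the GFP libraries and 0.868% and 0.926% in the CPEB4 libraries, and the 50 highest genes of each library held 18.8% and 20.6% against 14.9% and 15.6%. Across tested genes, which are not independent replicates, log2 CPM correlated at r = 0.964 between the GFP libraries, at 0.988 between the CPEB4 libraries and at 0.911 to 0.919 between the groups.

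Cpeb4 itself rose in both libraries of the CPEB4 virus. The gene (ENSMUSG00000020300.14, protein coding, plus strand of chromosome 11 from 31872211 to 31935634 in mm10) had 222 and 74 counts in the GFP libraries and 15234 and 19206 counts in the CPEB4 libraries. Its level was 8.43 ± 4.86 CPM (SD, n = 2) with GFP virus and 521 ± 17.7 CPM (SD, n = 2) with CPEB4 virus, a log2 fold change of 5.94 ± 0.42 (SE; edgeR adjusted p = 4.95e-05). Counts per gene do not separate reads of the viral transcript from those of the mouse's own gene.

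After CPEB4 virus infection 2160 of 16870 tested genes rose and 2163 fell (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Changes of at least 2-fold were found in 1667 genes that rose and 1529 that fell, and changes of at least 8-fold in 263 and 270. Among genes with a mean of at least 5 CPM the 8-fold changes were 19 upward and 178 downward. The groups did not overlap in any of the 4323 called genes, nor in 66.9% of tested genes, where chance gives 33.3% for 2 against 2. With 1 library left out, the spread within groups comes from the pair left whole. The biological coefficient of variation was 28.9% within the GFP pair and 11.6% within the CPEB4 pair. Call numbers in these fits therefore follow which pair was left whole, and do not measure robustness. Calls depended in this way on the library left out. They numbered 4342 higher and 4226 lower without GFP library 1 and 3788 and 3622 without GFP library 2. They numbered 756 and 799 without CPEB4 library 1 and 748 and 851 without CPEB4 library 2. Of the calls 50% were upward with TMM scaling and 68.3% or 67.6% on the deposited FPKM values. With library totals alone, a scaling chosen after seeing the data, 80.7% were upward and the median of all genes was 0.447 on the log2 scale.

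Of the 12 rising genes with the smallest p-values Krt18, a keratin of simple epithelia, rose from 0.720 ± 0.414 to 81.6 ± 0.762 CPM (SD, n = 2), a log2 fold change of 6.86 ± 0.35 (SE; edgeR adjusted p = 1.92e-05). Cyb561, a transmembrane electron carrier of secretory vesicles, rose by 5.79 ± 0.30 on the log2 scale. Cd34, a surface sialomucin found on quiescent satellite cells and other progenitors, rose from 27.9 ± 0.903 to 289 ± 7.12 CPM, a log2 fold change of 3.38 ± 0.22. The adhesion molecule gene Nrcam rose by 3.27 ± 0.21, the sphingosine 1-phosphate receptor gene S1pr3 by 3.90 ± 0.28, the membrane-bound chemokine gene Cx3cl1 by 2.95 ± 0.24 and the placental growth factor gene Pgf by 2.60 ± 0.22 on the log2 scale. The others were Cpeb4, B3galt4 (3.57 ± 0.30), Map6 (2.62 ± 0.23), P3h2 (3.26 ± 0.29) and Cpe (3.06 ± 0.27), the last encoding a prohormone-processing carboxypeptidase. All 12 had edgeR adjusted p-values of 0.000159 or less.

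Of the 12 falling genes with the smallest p-values Actc1, the cardiac actin that developing skeletal muscle also makes, fell from 1826 ± 185 to 14.5 ± 1.17 CPM (SD, n = 2), a log2 fold change of -6.98 ± 0.30 (SE; edgeR adjusted p = 1.75e-05). Ckm, the muscle creatine kinase, fell from 87.5 ± 4.91 to 1.52 ± 0.0847 CPM, a log2 fold change of -5.85 ± 0.25. The muscle LIM protein gene Csrp3 had a log2 fold change of -6.47 ± 0.32, the sarcomere-associated Klhl41 -5.19 ± 0.27, the stretch-responsive Ankrd2 -4.77 ± 0.24 and Mustn1 -4.66 ± 0.23. Mstn, which encodes the muscle growth inhibitor myostatin, fell from 46.3 ± 6.54 to 0.643 ± 0.215 CPM, a log2 fold change of -6.13 ± 0.32. The remaining genes of the 12 were Smim5 (-6.67 ± 0.28), Dbh, the noradrenaline-forming hydroxylase (-6.04 ± 0.31), Fgfbp1, a carrier of fibroblast growth factors (-5.17 ± 0.25), the calcium channel subunit gene Cacng6 (-5.02 ± 0.26) and the polarity gene Scrib (-4.14 ± 0.22). All 12 had edgeR adjusted p-values of 1.92e-05 or less. Each of these 12 and of the 12 rising genes kept its call in every alternative fit that was run.

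**Figure D1:**
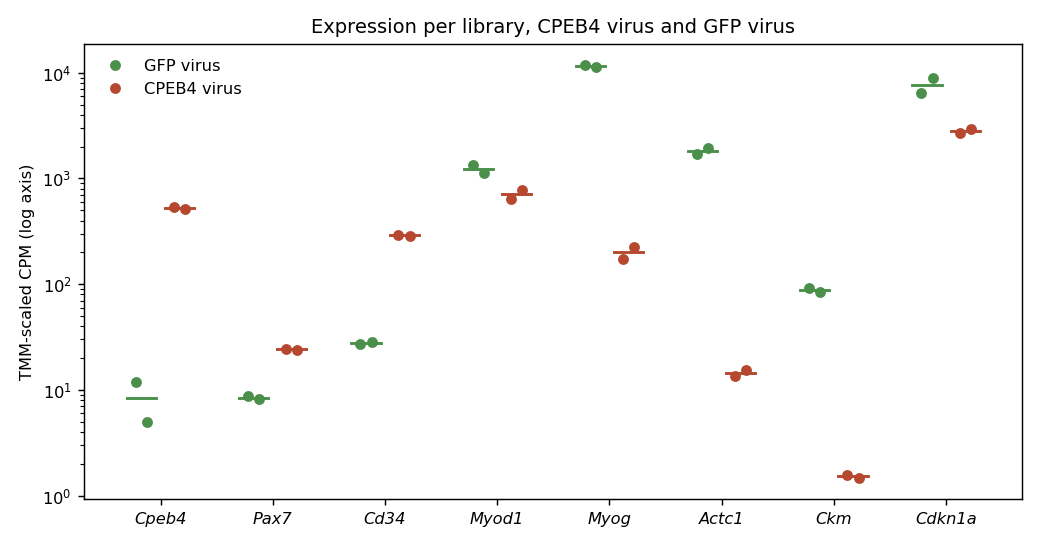
Expression of 8 genes in each library, as TMM-scaled CPM on a log axis; points are libraries (2 per group) and short lines the group means. Myog lay near 11660 CPM in the GFP libraries and near 200 CPM in the CPEB4 libraries, while Cpeb4, Pax7 and Cd34 lay higher in both CPEB4 libraries.

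Gene lists were fixed before the data were examined, and 37 were tested with camera, which compares a list with all other genes. With the preset correlation 6 lists rose and 12 fell. With a correlation estimated per list no call remained, and the camera adjusted p-values of these 18 lists lay between 0.43 and 0.85. A design of 2 libraries per group leaves few degrees of freedom for that estimate. The loss of every call therefore hardly tells robust lists from others. Of 129 list members singled out for the smallest p-values in their lists and called, 128 kept the call without either GFP library. The exceptions were Coro1a without GFP library 1 and Rpl22 without GFP library 2. Without CPEB4 library 1 the call was kept by 69 and without CPEB4 library 2 by 74. The call was kept by 86 and 85 on log2(FPKM + 1) and log2(FPKM + 0.1) (11 not tested on either), by 104 with a mean of at least 5 CPM (13 not tested), by 115 with upper-quartile scaling and by 98 with library totals alone. Other settings kept at least 123. None of the 129 changed sign under any alternative that tested it. They were chosen for small p-values in these same libraries, and the groups did not overlap in any called gene. A change of sign was therefore hardly possible. Calls kept or lost with 1 library left out also follow which pair was left to set the spread. With a gene counted in each of its lists, 118 members rose and 204 fell with all 4 libraries, 207 and 482 without GFP library 1, 193 and 315 without GFP library 2, 64 and 78 without CPEB4 library 1 and 52 and 91 without CPEB4 library 2. Of 16 lists with 0 calls in a direction, 10 had a call there without GFP library 1 and 8 without GFP library 2.

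Several list calls also depended on the filter, the scaling or the scale. With a mean of at least 5 CPM complex I (camera adjusted p = 0.144), the mitochondrial ribosome (0.248), endoplasmic reticulum stress (0.259) and the extracellular matrix (0.0741) were not called. On log2(FPKM + 1) and log2(FPKM + 0.1) the mitochondrial ribosome (0.408 and 0.355), endoplasmic reticulum stress (0.0829 and 0.0949) and the extracellular matrix (0.26 and 0.267) were not called. Upper-quartile scaling ended the calls of the mitochondrial ribosome (0.0555) and endoplasmic reticulum stress (0.0666), and the replicate block ended the latter (0.0815). With no count filter the NF-kB list was not called (0.0657). That setting called 6 lists lower that were not called with the filter and all 4 libraries, namely satellite cell quiescence (0.0102), mitochondrial chaperones, proteases and import (6.49e-06), fatty acid oxidation (0.0268), mitosis (1.74e-05), the integrated stress response (0.000186) and translation factors (0.000742). The medians of these lists hardly moved, as with quiescence (-0.107 against -0.096) and mitosis (-0.327 against -0.320). The median of all genes, with which camera compares a list, was 0.825 without the filter and -0.004 with it. Among alternatives chosen after seeing the data, library totals alone ended the calls of the mitochondrial ribosome (0.238), endoplasmic reticulum stress (0.123) and endothelial markers (0.0665). Removing the exon-length trend ended those of complex I and the mitochondrial ribosome (0.111 each) and called mitochondrial genome mRNAs higher (0.0416) and mitochondrial chaperones, proteases and import (0.0433) and mitosis (0.0319) lower. Removing the GC trend called the integrated stress response lower (0.0329).

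Genes of muscle differentiation fell together. In the sarcomere and muscle differentiation list 31 of 32 tested members fell and 0 rose, the same number adjusted over the list alone. The median log2 fold change was -3.83 (camera adjusted p = 9.88e-64, adjusted p = 0.427 with an estimated correlation). Besides Ckm and Actc1 the leading members were the myoglobin gene Mb (-4.72 ± 0.26) and the fast troponin T gene Tnnt3, which fell from 719 to 21.5 CPM (-5.06 ± 0.28). The member not called, Myh2, had a log2 fold change of -0.91 (edgeR adjusted p = 0.467). In the myogenic commitment list 14 of 18 members fell and 0 rose, 14 and 1 adjusted over the list alone. Their median was -2.10 (camera adjusted p = 1.16e-19, adjusted p = 0.427 with an estimated correlation). Myog, the transcription factor of terminal differentiation (chromosome 1, 134289989 to 134292548), fell from 11660 ± 377 to 200 ± 37.4 CPM (SD, n = 2), a log2 fold change of -5.87 ± 0.33 (SE; edgeR adjusted p = 2.25e-05). The fusion genes Mymx and Mymk fell by 5.52 ± 0.30 and 4.51 ± 0.30 on the log2 scale. Cav3, the muscle caveolin, had a log2 fold change of -4.26 ± 0.25. Myod1, the determination factor, had a log2 fold change of -0.80 ± 0.24 (edgeR adjusted p = 0.0398). It lost this call in 7 alternative fits, among them those without CPEB4 library 1 (adjusted p = 0.489) and CPEB4 library 2 (0.2). Myf5, chosen after its values were seen, had 0.27 ± 0.21 (edgeR adjusted p = 0.363).

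Stem cell genes moved in both directions. Pax7, the transcription factor that marks satellite cells (chromosome 4, 139737062 to 139833528), rose from 8.42 ± 0.348 to 24.1 ± 0.554 CPM (SD, n = 2), a log2 fold change of 1.52 ± 0.22 (SE; edgeR adjusted p = 0.00224). Of 29 tested members of the satellite cell quiescence list 5 rose (Cd34, Pax7, Tenm4, Foxo3 and Vcam1) and 8 fell. Adjusted over the list alone, 7 and 9 did so, and the list was not called (median -0.10, camera adjusted p = 0.177). Those that fell included Mstn, the Notch target Heyl (-2.61 ± 0.23) and the cyclin-dependent kinase inhibitor gene Cdkn1c (-3.59 ± 0.33). In the Notch pathway list Jag1 (1.12 ± 0.22) and Notch2 rose and 4 of 14 members fell (Heyl, Hey1, the ligand gene Dll1 at -2.12 ± 0.25 and Hes6 at -2.60 ± 0.26), the same counts adjusted over the list alone (camera adjusted p = 0.145).

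The TCA cycle and glycolysis lists were called lower, and both calls were lost without CPEB4 library 1. Of 22 tested genes of the TCA cycle 9 fell and Pcx rose, 14 and 1 adjusted over the list alone. The list median was -0.68 (camera adjusted p = 0.0153, adjusted p = 0.692 with an estimated correlation; 0.0585 without CPEB4 library 1 and 0.0789 with a mean of at least 5 CPM). Idh2, the mitochondrial isocitrate dehydrogenase, fell from 468 to 182 CPM (-1.36 ± 0.22), and Sdhc (-1.21 ± 0.22), Suclg2 (-0.94 ± 0.19) and Idh3a (-1.10 ± 0.23) fell as well. Of 20 glycolysis genes 7 fell and 0 rose, 8 and 0 adjusted over the list alone. The median was -0.64 (camera adjusted p = 0.0316, adjusted p = 0.672 with an estimated correlation; 0.134 without CPEB4 library 1, 0.0665 with library totals alone, 0.145 with a mean of at least 5 CPM, and 0.101 and 0.125 on log2(FPKM + 1) and log2(FPKM + 0.1)). Eno3, the muscle enolase, fell by 1.40 ± 0.25, the phosphofructokinase gene Pfkm by 1.36 ± 0.25, Tpi1 by 1.29 ± 0.25 and the lactate transporter gene Slc16a3 by 1.46 ± 0.23 on the log2 scale. In fatty acid oxidation 5 of 18 genes fell (Etfa at -1.59 ± 0.24, Acadm at -1.20 ± 0.19, Acadl, Hadhb and Echs1) and 3 rose (Acads, Pdk4 and Cpt1a), 8 and 5 adjusted over the list alone (camera adjusted p = 0.399).

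The nuclear genes of the respiratory chain and of the ribosomes lay lower as lists, with single calls that depended on the libraries used. Call counts with 1 library left out also follow which pair was left to set the spread. Of 36 complex I genes 2 fell (Ndufc2 at -0.93 ± 0.28 and Ndufs4 at -0.90 ± 0.27) and 0 rose, 0 and 0 adjusted over the list alone. Their median was -0.59 (camera adjusted p = 0.0256, adjusted p = 0.786 with an estimated correlation). Of 40 nuclear genes of complexes II to V 6 fell and 0 rose, 1 and 0 adjusted over the list alone. The list median was -0.71 (camera adjusted p = 0.00224, adjusted p = 0.748 with an estimated correlation). Sdhd (-0.78 ± 0.23), Atp5f1 (-0.85 ± 0.26) and the cytochrome c gene Cycs (-1.17 ± 0.36) were among them with Sdhc. Of 76 cytosolic ribosomal protein genes 4 fell (Rpl27 at -1.12 ± 0.33, Rpl3, Rps29 and Rpl22) and 0 rose, 0 and 0 adjusted over the list alone. The median was -0.65 (camera adjusted p = 0.00224, adjusted p = 0.786 with an estimated correlation). Of 72 mitochondrial ribosome genes 9 fell, among them Mrpl3, Mrpl32, Mrps14 and Mrps16, and 0 rose, 0 and 0 adjusted over the list alone. The list median was -0.31 (camera adjusted p = 0.0357, adjusted p = 0.848 with an estimated correlation). It turned to 0.16 with library totals alone, where the list was not called (camera adjusted p = 0.238). On log2(FPKM + 1) and log2(FPKM + 0.1) it was 0.064 and 0.069, with 2 members higher in each and 1 and 0 lower. With library totals alone the medians of complex I, complexes II to V and ribosomal proteins were -0.096, -0.229 and -0.152, with 0.447 for all genes. On log2(FPKM + 1) these medians were -0.142, -0.281 and -0.182, with 0.161 for all genes. Without GFP library 2 the medians were -0.03 for complex I, -0.10 for complexes II to V, 0.022 for ribosomal proteins and 0.00 for the mitochondrial ribosome, with camera adjusted p-values of 0.941, 0.114, 0.998 and 0.723. Without GFP library 1 the medians were -1.01, -1.09, -1.10 and -0.61, with 33 of 36, 38 of 40, 74 of 76 and 46 of 72 members lower, against 5, 10, 4 and 14 lower without GFP library 2 and 0 in each list without either CPEB4 library. Members higher numbered 0, 0, 1 and 1 without GFP library 1 and 3, 0, 2 and 9 without GFP library 2. Without CPEB4 library 1 the mitochondrial ribosome was not called (camera adjusted p = 0.0638).

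**Figure D2:**
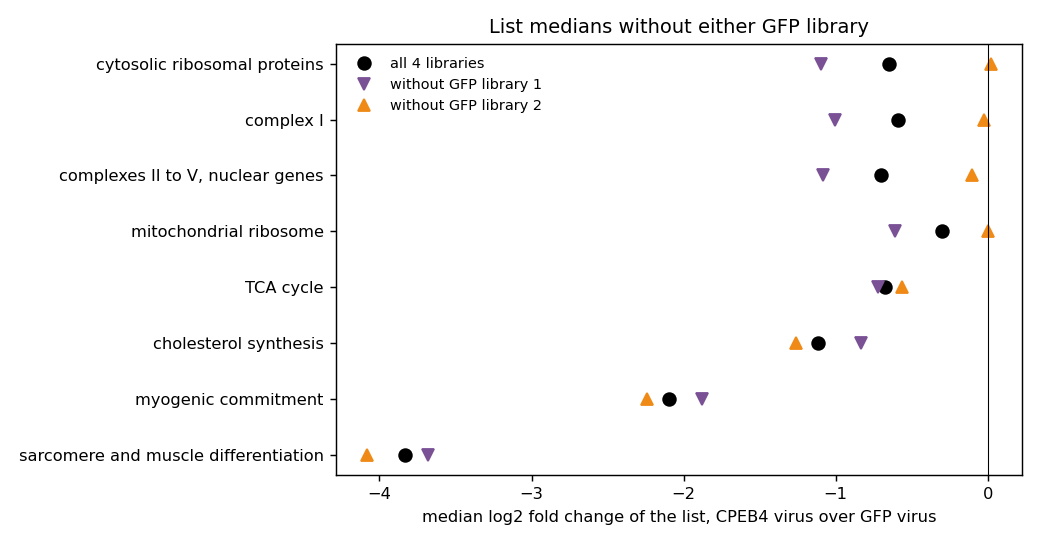
Median log2 fold change (CPEB4 virus over GFP virus) of 8 gene lists with all 4 libraries (circles), without GFP library 1 (downward triangles) and without GFP library 2 (upward triangles). Ribosomal proteins, complexes I to V and the mitochondrial ribosome lay between -0.10 and 0.022 without GFP library 2, while the sarcomere list stayed at -3.68 or lower; with library totals alone as the scaling the mitochondrial ribosome median was 0.16.

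Other mitochondrial and translation lists were not called with all 4 libraries. Among 12 mRNAs of the mitochondrial genome mt-Nd5 (1.08 ± 0.22) and mt-Nd6 (0.90 ± 0.28), which overlap on opposite strands and cannot be told apart there without strand, rose and 0 fell, 1 and 0 adjusted over the list alone. The list was not called (median 0.01, camera adjusted p = 0.491), while the share of counts from the mitochondrial genome was higher in both CPEB4 libraries (0.868% and 0.926% against 0.567% and 0.539%). The list median was 0.475 with library totals alone, 0.370 and 0.382 on log2(FPKM + 1) and log2(FPKM + 0.1), -0.002 with DESeq2 size factors and -0.118 with the GC trend removed, and the list was not called in these. It was called higher with the length trend removed (median 0.369, adjusted p = 0.0416) and without GFP library 2 (0.370, adjusted p = 0.0327), but not without GFP library 1 (-0.126) or CPEB4 library 2 (-0.052). Of 29 mitochondrial chaperone, protease and import genes 5 fell (Tomm20 at -1.06 ± 0.23, Timm23, Yme1l1, Tomm22 and Hspe1) and 0 rose, 1 and 0 adjusted over the list alone (camera adjusted p = 0.0839; 0.00171, 0.0218 and 0.0221 without GFP library 1, GFP library 2 and CPEB4 library 2). Of 14 biogenesis regulators Pprc1, a coactivator related to PGC-1alpha, rose by 1.54 ± 0.26, Polg rose by 0.84 ± 0.22 and Gabpa fell (-0.75 ± 0.21). Adjusted over the list alone 2 were higher and 4 lower (camera adjusted p = 0.834). Of 29 translation factors Eif4a1 (-1.04 ± 0.22) and Eif3e (-0.74 ± 0.23) fell and 0 rose, 1 and 0 adjusted over the list alone (camera adjusted p = 0.271; 0.0208 without GFP library 1). The translation factor median of -0.333 was 0.129 with library totals alone. On log2(FPKM + 1) and log2(FPKM + 0.1) it was 0.013, with 2 members higher and 0 lower in each. In the list of the CPEB family and polyadenylation machinery Cpeb4 and Zfp36l2 (2.21 ± 0.37) rose and Tob1 (-1.48 ± 0.21), Nudt21 (-0.98 ± 0.21) and Cnot8 fell among 36 members. These were 2 and 2 adjusted over the list alone (camera adjusted p = 0.922). The list median of -0.03 differed in sign from its mean of 0.10 and from camera's direction.

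Cell cycle lists were not called, and the inhibitor Cdkn1a fell. Differentiation genes such as Myog fell in the same libraries. Whether the fall of Cdkn1a goes with them, with p53 or with senescence was not tested. Cdkn1a, the p53 target that encodes p21 (chromosome 17, 29090976 to 29100727), fell from 7668 ± 1801 to 2802 ± 171 CPM (SD, n = 2), a log2 fold change of -1.45 ± 0.28 (SE; edgeR adjusted p = 0.00738, and 0.073 without CPEB4 library 1). Cdkn2a, the senescence-associated locus, had 7 and 14 counts with GFP virus and 11 and 15 with CPEB4 virus. No difference was detectable at this depth (-0.72 ± 0.67, edgeR adjusted p = 0.456). Mki67, the proliferation marker, had 36.8 ± 12.1 and 45.3 ± 0.240 CPM (SD, n = 2; log2 fold change 0.30 ± 0.25, edgeR adjusted p = 0.4). Without GFP library 1 it was called at 0.69 (adjusted p = 0.000414). Of 32 S phase genes 6 rose, led by the licensing factor gene Cdt1 (1.34 ± 0.20), Chaf1b (0.92 ± 0.20), Gins3 and Chaf1a, and Rrm2 and Dut fell, 7 and 2 adjusted over the list alone (camera adjusted p = 0.231; called higher at 0.0123 and 0.0279 on log2(FPKM + 1) and log2(FPKM + 0.1), with 9 members higher and 0 lower in each). Of 30 mitosis genes 4 fell (Cdc20 at -1.08 ± 0.22, Ccnb2 at -0.95 ± 0.22, Bub3 and Cenpa) and 0 rose, 3 and 0 adjusted over the list alone (camera adjusted p = 0.105; 0.00165 without GFP library 2 and 0.0253 without CPEB4 library 2). Of 25 senescence-associated inhibitors and p53 targets 6 fell, among them Cdkn2d (-1.58 ± 0.20), Gadd45b (-1.48 ± 0.22) and Cdkn2c (-1.35 ± 0.28), and 4 rose (Zmat3, Sesn2, Aen and Phlda3), 7 and 7 adjusted over the list alone (camera adjusted p = 0.524).

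Lists of interferon-induced, secreted, inflammatory and immediate early genes were called higher by camera, with many members not called singly. Of 28 type I interferon response genes 14 rose and 0 fell, 18 and 2 adjusted over the list alone. These counts were 17 and 3 without GFP library 1, 17 and 6 without GFP library 2, 8 and 0 without CPEB4 library 1 and 7 and 0 without CPEB4 library 2. With all 4 libraries the list median was 1.07 (camera adjusted p = 0.00146, adjusted p = 0.495 with an estimated correlation). Ifi35 rose from 42.6 to 120 CPM. The transcription factor genes Irf9 (1.77 ± 0.28) and Irf7 (2.17 ± 0.38) and the nucleic acid sensor gene Zbp1 (2.22 ± 0.37) rose from under 5 CPM. Oas3, chosen after its values were seen, had 0 counts in the GFP libraries and 57 in the CPEB4 libraries, at least 9.61-fold higher against a floor of 3 counts over the group. Of 38 senescence-associated secretory factors 14 rose and 6 fell, 17 and 6 adjusted over the list alone. The list median was 0.52 (camera adjusted p = 0.0256, adjusted p = 0.587 with an estimated correlation; 0.0566 without GFP library 1, 0.0786 without CPEB4 library 2, 0.103 with no count filter, 0.0758 with a mean of at least 5 CPM, and 0.105 and 0.154 on log2(FPKM + 1) and log2(FPKM + 0.1)). Spp1, which encodes osteopontin, rose from 1268 to 4898 CPM (1.95 ± 0.26), Csf1 from 139 to 601 CPM (2.11 ± 0.28) and Cxcl12 by 1.51 ± 0.19. The protease gene Mmp10 had 1 count against 210, a ratio of 106 (95% exact interval 18.9 to 4210). Of 23 NF-kB and inflammatory genes 10 rose and 4 fell (Il1b, Sod2, Tnfaip2 and Cxcl1), 13 and 4 adjusted over the list alone. The median was 0.64 (camera adjusted p = 0.0256, adjusted p = 0.672 with an estimated correlation; 0.118 without CPEB4 library 2). Birc3 (2.34 ± 0.26), Traf1 (2.04 ± 0.25), the NF-kB subunit gene Nfkb2 (1.77 ± 0.22) and the adhesion gene Icam1 (1.99 ± 0.27) led it. Of 25 immediate early genes 10 rose and Dusp1 and Jund fell, 12 and 3 adjusted over the list alone. Their median was 0.89 (camera adjusted p = 0.00582, adjusted p = 0.672 with an estimated correlation). The orphan receptor genes Nr4a1 (2.99 ± 0.29) and Nr4a2 (2.79 ± 0.38) led, with Klf6 (1.34 ± 0.21) and Fosl1 (1.34 ± 0.21).

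The lists of cholesterol synthesis, cytosolic chaperones and endoplasmic reticulum stress were called lower. Of 24 cholesterol synthesis genes 18 fell and 0 rose, 19 and 0 adjusted over the list alone. The list median was -1.12 (camera adjusted p = 9.48e-10, adjusted p = 0.427 with an estimated correlation). The isopentenyl diphosphate isomerase gene Idi1 fell from 172 to 38.1 CPM (-2.17 ± 0.21) and the squalene synthase gene Fdft1 from 402 to 99.0 CPM (-2.02 ± 0.24), and Hsd17b7 (-1.73 ± 0.20) fell too. Of 22 cytosolic chaperones 13 fell and 0 rose, 15 and 0 adjusted over the list alone. The median was -0.80 (camera adjusted p = 2.1e-05, adjusted p = 0.66 with an estimated correlation). The small heat shock genes Hspb8 (1803 to 84.3 CPM, -4.42 ± 0.36), Cryab (-2.23 ± 0.24) and Hspb1 (-2.18 ± 0.28) led, and muscle expresses all 3 strongly. Hsp90aa1 followed (-1.05 ± 0.23). Of 25 endoplasmic reticulum stress genes 9 fell, led by Herpud1 (-2.30 ± 0.23), Pdia4, Creld2 and Dnajb9, and Ern1 and Edem1 rose, 10 and 2 adjusted over the list alone. The list median was -0.43 (camera adjusted p = 0.0473, adjusted p = 0.587 with an estimated correlation), and the call was lost without CPEB4 library 1. The median turned to 0.03 with library totals alone, where the list was not called (camera adjusted p = 0.123). In the integrated stress response 7 of 24 genes fell, led by the hormone gene Fgf21 (265 to 7.46 CPM, -5.14 ± 0.34), Mthfd2 (-1.16 ± 0.20), Slc7a5 and Asns, and 4 rose (Gdf15, Sesn2, Ddit4 and Ddit3), 11 and 4 adjusted over the list alone (camera adjusted p = 0.0687; 0.00182 without GFP library 2 and 0.0164 without CPEB4 library 2).

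Oxidative stress and lysosome lists went both ways with TMM scaling and were not called. Of 25 oxidative stress genes Srxn1 (1.66 ± 0.23), G6pdx (1.20 ± 0.21) and Gclm rose and Sod2 (-1.13 ± 0.24), Prdx1 (-1.11 ± 0.25) and Cat fell, the same counts adjusted over the list alone (camera adjusted p = 0.879). Of 34 autophagy and lysosome genes 6 rose, among them the lysosomal hydrolase gene Hexa (1.32 ± 0.20) and the channel gene Mcoln1, and 5 fell (the mitophagy receptor gene Bnip3 at -2.16 ± 0.20, Gabarapl2, Map1lc3a, Becn1 and Atg5), 7 and 7 adjusted over the list alone (camera adjusted p = 0.879). Their median was -0.09 against a mean of 0.01, and 0.381 with library totals alone. On each of log2(FPKM + 1) and log2(FPKM + 0.1) 7 of these genes rose and 1 fell, and 4 oxidative stress genes rose and 1 fell.

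Matrix genes rose more often than they fell. Of 32 extracellular matrix genes 12 rose and 5 fell, 14 and 5 adjusted over the list alone. The list median was 0.70 (camera adjusted p = 0.0312, adjusted p = 0.702 with an estimated correlation). It was 0.40 without GFP library 2 (adjusted p = 0.249) and 1.06 without GFP library 1. The call was also lost after removing each library's trend with exon length, chosen after seeing the data (adjusted p = 0.118). The tenascin gene Tnc rose from 23.2 to 197 CPM (3.08 ± 0.28) and the decorin gene Dcn by 1.98 ± 0.28, while Thbs1 fell from 638 to 145 CPM (-2.13 ± 0.32) and Col1a2 by 1.45 ± 0.20, with Postn, Col5a1 and Nid2. Of 21 TGF-beta targets 5 rose (Ccn2 at 2.53 ± 0.24, Ltbp2 at 2.07 ± 0.31, Tgif1, Pmepa1 and Tgfbi) and 2 fell, Cdkn1a and the actin gene Acta2 (3787 to 608 CPM, -2.64 ± 0.27), 8 and 3 adjusted over the list alone (camera adjusted p = 0.247).

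Markers of other cell types that a sort could hold moved beside the higher olfactory receptor reads of the CPEB4 libraries given above. Of 20 listed endothelial markers 9 passed the count filter. Emcn, Flt1 and Kdr (3 counts against 45) passed only through the CPEB4 libraries, which favours a higher list. With a mean of at least 5 CPM 3 members remained, too few for camera. Of the 9 tested endothelial markers 2 rose and 0 fell, 4 and 0 adjusted over the list alone. The median was 0.83 (camera adjusted p = 0.0335, adjusted p = 0.587 with an estimated correlation; 0.0827 with a median of 1.43 without GFP library 2, and a median of 1.49 without GFP library 1). Emcn had 0 counts against 51, at least 8.60-fold higher against 3 counts over the group, and Flt1 had 3 counts against 97, a ratio of 16.3 (95% exact interval 5.43 to 80.7). With a background estimated on receptor genes subtracted, the endothelial median was 0.752 against 0.825 before, that of the mitochondrial ribosome -0.282 against -0.305 and that of endoplasmic reticulum stress -0.406 against -0.429. None of the 3 was then called (adjusted p = 0.071 each), though the medians hardly moved, with 8 endothelial markers tested. Of 13 smooth muscle and pericyte markers 4 fell (Mustn1, Acta2, Des at -1.28 ± 0.25 and Abcc9 at -3.04 ± 0.53) and 0 rose, the same counts adjusted over the list alone. Their median was -0.18 (camera adjusted p = 0.0256, adjusted p = 0.587 with an estimated correlation). The call was lost without GFP library 1 and without CPEB4 library 2. The median was 0.27 with library totals alone (camera adjusted p = 0.00897) and 0.01 without CPEB4 library 2. Without CPEB4 library 1 that median was -0.47. Of these 4 genes at least Mustn1, Acta2 and Des are also known in developing or regenerating skeletal muscle. The fall of the 4 therefore does not single out smooth muscle cells or pericytes.

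The other marker lists were not called. Of 16 fibro-adipogenic progenitor markers 4 rose and Col1a2 fell, 4 and 2 adjusted over the list alone (camera adjusted p = 0.271). Smoc2 (2.51 ± 0.38) and Dcn rose, Pdgfra had 2 counts against 114, a ratio of 28.8 (95% exact interval 7.80 to 241), and Lum had 3 against 41, a ratio of 6.91 (2.20 to 34.9). Of 10 macrophage and leukocyte markers Cd14 (3.03 ± 0.31), Cd68 (1.93 ± 0.30) and Coro1a rose and H2-Ab1 fell, 3 and 1 adjusted over the list alone (camera adjusted p = 0.145; 0.026 without CPEB4 library 2). Of 11 Schwann cell markers Ngfr rose and Cnp fell, and of 5 tenocyte markers Thbs4 rose and Scx, a tendon transcription factor, fell by 2.67 ± 0.33, 1 and 1 adjusted over the list alone in each (camera adjusted p = 0.582 and 0.984). No erythroid marker passed the count filter.

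**Figure D3:**
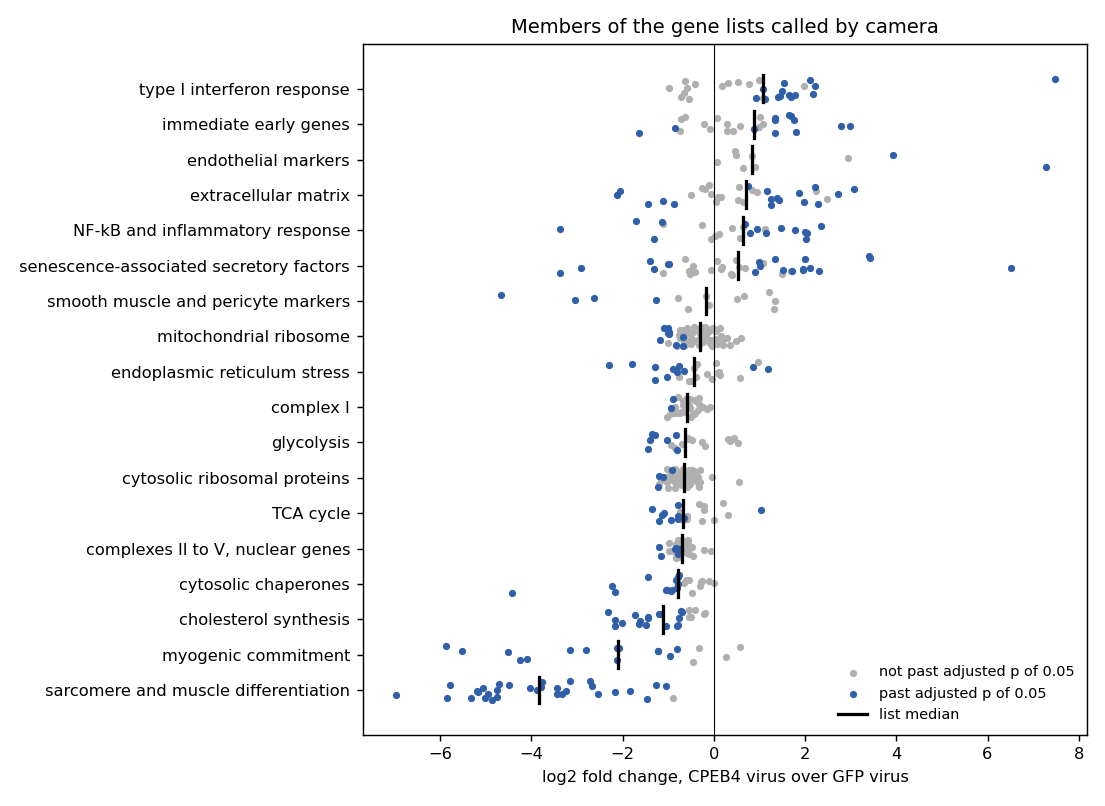
Log2 fold changes (CPEB4 virus over GFP virus) of the tested members of the 18 lists called by camera; each point is a gene, blue where its edgeR adjusted p is under 0.05 and grey otherwise, and each bar is the list median. The medians run from -3.83 in the sarcomere list to 1.07 in the interferon list, and those of the mitochondrial ribosome, endoplasmic reticulum stress and smooth muscle lists turn positive with library totals alone as the scaling.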

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

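The tests of depth and of reads spread over the genome were chosen after the receptor reads had been seen, and the background subtraction was an alternative added after the data were seen. Olfactory receptor genes held 227 CPM of the total in CPEB4 library 1 and 62.1 in CPEB4 library 2, above the 28.7 and 27.8 of the GFP controls, and the share of the FPKM library total outside the counted genes was 26% and 19.1% against 16% and 16.7%. Both were singled out as signals outside the main measurement that exceed their level in the control libraries. Deeper sequencing was argued against, since after thinning to equal totals the lower CPEB4 library still held 2.22 times the olfactory reads of the higher GFP library. An even background that makes most of the upward calls was argued against as well, since 97.1% of them remained after its subtraction. The subtraction took 0.505% and 0.122% of the counts of CPEB4 libraries 1 and 2, at 1.04 and 0.377 reads per exonic kb. It speaks only to a background of that density. Reads spread over the genome, such as those of genomic DNA, may contribute but stay open, because vomeronasal receptor genes held 0.607 times the olfactory density per exonic kb in CPEB4 library 1, a ratio too far from 1 for an even spread by the bound set and too near for its exclusion, and unassigned reads were not analysed here. A broader transcription of receptor genes after CPEB4 virus infection was not tested and stays open too.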

How the results depend on the processing

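Library totals, exon length, GC content and background subtraction were alternatives chosen after seeing the data. Cpeb4 stayed higher in all of the settings run, with log2 fold changes of 5.28 to 6.72. Leaving out 1 library gave 748 to 4342 higher and 799 to 4226 lower genes, where the lone sample of a group is assumed to vary like the other group, and 5 to 6 lists higher and 8 to 14 lower. Lower genes numbered 890 on log2(FPKM + 1) and 861 on log2(FPKM + 0.1), and library totals alone gave 4237 higher and 1011 lower genes. The cause was not tested, but the last setting moves all fold changes up together. A mean of at least 5 CPM gave 3 lists higher and 7 lower, with fewer genes tested (10157), and an estimated correlation gave 0 and 0 lists, in a design with few degrees of freedom. The median of ribosomal proteins reversed to 0.022 without GFP library 2 and was -1.097 without GFP library 1. The labels do not say whether libraries with the same replicate number share an animal or a day. The correlation of same-numbered deviations, 0.076, does not settle it. The fit with the replicate block called 2701 higher and 2491 lower genes and 6 and 11 lists, losing endoplasmic reticulum stress. Of the other comparisons with an alternative, 439 of named genes stayed on the same side of the threshold, 8 lost the call and 1 gained it. For lists 493 stayed on the same side, 64 lost the call and 22 gained it. Direction changed in some of these without a call. Mki67 had -0.01 without GFP library 2 against 0.30, and the oxidative stress median was 0.314 with library totals alone against -0.142. The median of mitochondrial genome mRNAs was -0.126 without GFP library 1 against 0.012. Depth limits genes under about 10 counts, and 2 libraries per group limit small changes. In the simulation 37.8% of 2-fold changes were recovered. It changed 194 of 16344 genes and gave both groups the same spread, where the real fit called 4323 of 16870. That share therefore does not carry over to these data.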

Other observations

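The genes and gene family in the next 2 paragraphs were chosen after their values were seen, as were the removal of the length trend and the tests of scaling, of fewer myogenic cells and of dilution by fibro-adipogenic cells below. Apart from that family they are single genes, and no pathway was tested on them. Sphk1, the kinase that makes sphingosine 1-phosphate, rose from 2.24 ± 0.748 to 23.1 ± 0.859 CPM (SD, n = 2; log2 fold change 3.38 ± 0.30, edgeR adjusted p = 0.000174). The receptor gene Egfr rose from 20.4 ± 5.34 to 111 ± 1.09 CPM (2.44 ± 0.24, edgeR adjusted p = 0.000272). Both genes were higher in both CPEB4 libraries than in either GFP library.

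The imprinted non-coding RNA H19 fell from 843 ± 180 to 30.9 ± 5.28 CPM (SD, n = 2; log2 fold change -4.77 ± 0.29, edgeR adjusted p = 2.78e-05), the imprinted Mest from 550 ± 55.4 to 68.4 ± 5.99 CPM (-3.01 ± 0.23) and the growth factor gene Igf1 from 60.8 ± 15.5 to 4.55 ± 1.18 CPM (-3.74 ± 0.29), while Hmga2, a chromatin protein gene of growing cells, rose from 2.68 ± 1.12 to 22.4 ± 1.96 CPM (3.04 ± 0.32). Among 160 families of genes grouped by symbol, 8 were called by camera and 0 with an estimated correlation (adjusted p = 0.979 for each of the 8). In the Psmd family of proteasome regulatory subunits 10 of 14 genes fell and 0 rose (median log2 fold change -0.81, camera adjusted p = 0.0164, adjusted p = 0.979 with an estimated correlation). The Psmd median was -0.36 with library totals alone, -0.77 without GFP library 2 and -0.78 without CPEB4 library 1, where the family was not called (camera adjusted p = 0.0617).

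Short, abundant mRNAs of ribosomes and the respiratory chain lay lower with CPEB4 virus, with a median of -0.59 over 224 genes of 4 lists. Exon length correlated across genes (Spearman) at 0.231 with the log2 fold change between groups. It correlated at -0.389 with GFP library 2 minus GFP library 1 and at -0.215 with CPEB4 library 2 minus CPEB4 library 1. Among the shortest genes the median was -0.549 between groups and 0.692 for GFP library 2 minus GFP library 1. A trend with union exon length was argued against as the whole cause, since the median was -0.49 once it was removed. That lay past a bound written before the removal was run. Without GFP library 2 the removal took the median from -0.018 to -0.265, away from 0. Union exon length is not the length of the mRNA made, so a trend with mRNA length stays open. At the preset correlation of 0.01 ribosomal proteins and complexes II to V stayed called after the removal (camera adjusted p = 0.0224 each). Complex I (median -0.588 before, -0.427 after with quartiles of -0.648 and -0.254) and the mitochondrial ribosome (-0.305 before, -0.299 after with quartiles of -0.638 and -0.006) did not (0.111 each), for a cause that was not tested. Before the removal the estimated correlations of ribosomal proteins and complexes II to V were 0.939 and 0.929. With these neither list was called (camera adjusted p = 0.786 and 0.748). Their members thus moved largely together, and the 2 calls add little against a length trend. A difference of GFP library 2 from its replicate is a candidate explanation, since the median was -0.02 without it and -0.97 without GFP library 1, yet the -0.265 left after removal of the length trend, where none of the 4 lists was called (0.27 to 0.882), leaves open how far the pattern rests on that library. Scaling stays open too, since the gap to the median of all genes with library totals alone (-0.55, and -0.16 without GFP library 2) hardly tests it when 1 factor per library moves all genes alike, and so does an effect of CPEB4 virus.

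The sarcomere and myogenic commitment lists were called lower with CPEB4 virus in every combination of libraries run (adjusted p = 0.427 for each with an estimated correlation), though of 18 commitment genes 9 and 10 were lower without CPEB4 libraries 1 and 2 against 14 with all, and 1 was higher without GFP library 1. Fewer myogenic cells were argued against as the whole cause, since Pax7, Myf5, Myod1, Cdh15 and Itga7 had a median log2 fold change of -0.80 against -3.83 for the sarcomere list. The same 5 genes argue against dilution by fibro-adipogenic cells as the whole cause. Of 6 transcripts such cells make in abundance Dcn rose (1.98 ± 0.28) and Lum rose (3 counts against 41, a ratio of 6.91 with a 95% exact interval of 2.20 to 34.9). Col1a2 fell (-1.45 ± 0.20), and Col1a1, Col3a1 and Gsn had -0.20 ± 0.33, -0.11 ± 0.21 and -0.39 ± 0.24 (SE), a median of -0.15 over the 6. In the whole marker list 4 of 16 rose, Smoc2 and Pdgfra (2 counts against 114) among them, and Col1a2 fell. The 6 transcripts therefore do not decide the share of such cells, and a partial dilution stays open. A trend with union exon length was argued against, since the sarcomere median was -3.84 once it was removed. An effect of CPEB4 virus on differentiation was not itself tested and stays open, as do differences in timing or handling between the groups, which the labels do not record.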
